A study of Homo sapiens with 50 samples.

How the data were processed

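RNA of H1 human embryonic stem cells and of their differentiating cultures was sequenced in 50 libraries, 2 for each of 25 groups of treatment and day. Per the labels, RNA was extracted with RNAiso Plus and libraries were made from 1 µg of total RNA with the VAHTS Universal V8 kit. Reads were processed with cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 on the GRCh37 build, per the submitters' processing notes, which name the tools but not the step or the settings of each. The deposited tables give, for 57905 Ensembl genes, 1 column of counts and 1 column of FPKM per library. The deposited FPKM were recomputed from the counts, the exonic gene sizes and the library totals, with a ratio of 1 for every library. One table holds days 3 and 5 (24 libraries) and the other days 7, 11 and 0 (26 libraries). Whether reads were counted by strand is not stated, so levels of genes that overlap another gene on the opposite strand are uncertain, as are those of near-identical genes. Coordinates are those of the deposited tables, on GRCh37.

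Samples were grouped by the treatment, day and replicate number in the labels. The test written before the data were examined was limma on log2(FPKM + 1), with edgeR to be used instead if raw counts were found. The tables hold counts, so edgeR 4.0.16 in R 4.3.3 was used and limma 3.58.1 became an alternative. Within each table, genes with at least 1 FPKM in at least 2 libraries were kept: 17286 genes on days 3 and 5 and 18451 in the other table, holding 99.57% and 99.63% of the counts. Counts were scaled by TMM and fitted with a robust quasi-likelihood model with 1 mean per group over all libraries of a table, so that the groups of 2 share 1 estimate of spread. The 2 libraries with 2-DG of day 3, which lay far apart, enter that estimate for every comparison of days 3 and 5. Group means, or for interactions the differences of group means, were compared with quasi-likelihood F tests and a Benjamini-Hochberg adjustment over the genes of a comparison. A gene was called at an adjusted p under 0.05 with a log2 fold change of at least 1 in size. Standard errors are the log2 fold change divided by the square root of F. A fold against a group with 0 counts in both libraries was computed against a floor of 3 counts per library.

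Of 42 gene lists fixed before the data were examined, 41 had at least 3 tested members, and skeletal muscle markers, which had fewer, were not tested. Members below the filter were left out. A gene silent in one group passes the filter only where another group expresses it, which favours rises from the silent group. Lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01) and adjusted over the lists of a comparison, with an estimated correlation and with fry as alternatives. Members were counted as called over all genes tested, and again with the adjustment made over the list alone. The list results given were chosen after all list tests were seen: of 1476 tests (41 lists in 36 comparisons), 626 were called with the preset correlation, and 159 of these with an estimated correlation. With fry, each list result given as called was also called. Fry asks whether a list changed at all, not whether it changed more than other genes. It called proton, bicarbonate and lactate transport genes in 24 of 36 comparisons where camera called them in 0, and whether that list truly changed was not settled. Since fry sets no list against other genes, its calls add little support to those of camera.

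Genes were named by a rule written before the data were examined: a panel of 26 genes; for each comparison and day the 3 called genes with the largest rise and the 3 with the largest fall, among those with at least 5 FPKM in the higher group and both libraries of one group above both of the other; and up to 4 called members of each list described, those with the largest change. PECAM1, a gene of the panel, is not analysed here. Only part of the 1009 results on genes so named are printed. The rule does not fix which, so the printed genes are examples and not an unselected set.

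Depth ran from 14794134 to 22796553 counts per library on days 3 and 5 and from 14090004 to 20445875 on the other days. The biological coefficient of variation was 0.1186 and 0.0669 in the 2 tables. The tests were tested on simulated data with 200 changed genes in 4 fold sizes. The changed genes were drawn only from those above a minimum expected count in the control, with the spread that had been fitted. The shares called do not hold for genes with lower counts. For HCl against control on day 3 (17286 genes) edgeR called 36%, 94%, 96% and 98% of genes changed 2-, 3-, 4- and 8-fold, with 1 unchanged gene called. For the same comparison on day 11 (18451 genes) it called 44%, 96%, 96% and 100%, with 4 unchanged genes called. Camera called the 1 changed list and 0 of the others in both. Simulated genes varied independently, so these draws cannot show list calls that come from correlation between genes. In the data that correlation was estimated at 0.603 for fibroblast and matrix genes on days 7, 11 and 0.

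The correlation of the HCl and IWP2 changes was set beside 100 draws of simulated counts in which both groups equalled the control they share, and the overlap of their calls beside 10 such draws, each fitted anew. The overlaps of calls for NaHCO3 beside IWP2 and for 2-DG were set beside 10 draws in which these groups equalled IWP2. The alternatives chosen before the data were examined were a pseudocount of 0.1 FPKM with limma, no filter, upper-quartile scaling, a fit on the days compared alone, a term for the replicate number, and each library left out in turn, where the lone library of a group is assumed to vary like the other groups. Limma on log2(FPKM + 1) was the test first written, and it was made an alternative once counts were found. Chosen after seeing the data were DESeq2 1.42.0, its size factors in edgeR and leaving mitochondrial genes out before scaling. Leaving out the first 2-DG library of day 3 was also chosen then. GC content for 1 check came from GENCODE v29 transcripts, matched by gene identifier for 16558 of 17286 genes (95.8%). No library was left out of the results given.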

Results

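H1 human embryonic stem cells, an established line, were profiled by RNA sequencing before differentiation and on days 3, 5, 7 and 11 of culture toward mesendoderm and heart muscle. The labels give 25 groups of 2 libraries, 50 libraries in all. Undifferentiated cells stand for day 0, and each later day has 6 treatments: a differentiation control, HCl, NaHCO3, IWP2, IWP2 with NaHCO3, and IWP2 with NaHCO3 and 2-DG. HCl is an acid, NaHCO3 (sodium bicarbonate) is a base, IWP2 blocks the secretion of WNT proteins, and 2-DG (2-deoxyglucose) is a glucose analogue that inhibits glycolysis. The labels give no doses, no times of addition and no pH readings. No group was given another acid, another base or a salt. Below, "acid" and "base" therefore stand for HCl and NaHCO3, and an effect of pH itself cannot be told apart from their other effects. Gene counts summed to between 14794134 and 22796553 per library on days 3 and 5, and to between 14090004 and 20445875 on the other days. The values were deposited in 2 tables, one for days 3 and 5 and one for days 7, 11 and 0. Every test was made within a table, and levels set side by side across the tables were not tested.

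Levels are deposited FPKM, given as mean ± SD of the 2 libraries of a group (SD, n = 2), and log2 fold changes come from the scaled counts. A gene was called when its edgeR quasi-likelihood test had a Benjamini-Hochberg adjusted p under 0.05 and its log2 fold change was at least 1 in size, and "rose" or "fell" is written only of called genes. Gene lists were fixed before the data were examined and tested with camera against all other genes. Where a list has 1 adjusted p, its call held when the correlation between its genes was estimated; where it did not hold, that p follows. The p-values measure the spread between these libraries only.

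**Figure D1:**
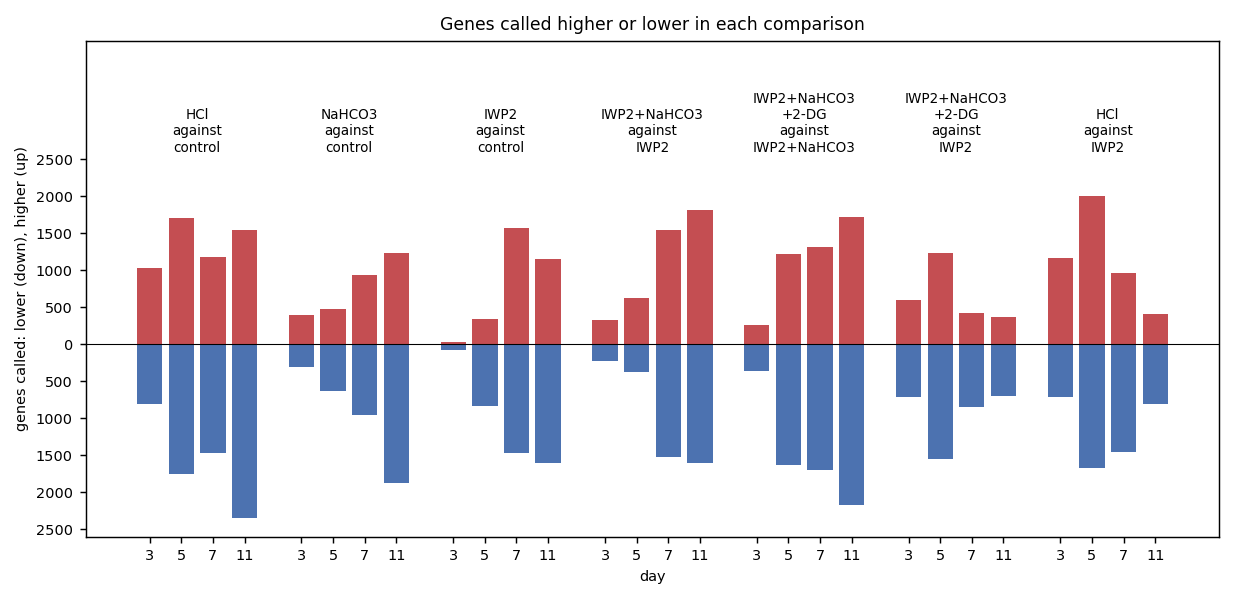
Number of genes called higher (upward bars) or lower (downward bars) in each of 7 comparisons on days 3, 5, 7 and 11, with 2 libraries per group. IWP2 against control has 28 higher and 78 lower on day 3, and 1151 higher and 1602 lower on day 11. Days 3 and 5 were fitted apart from days 7 and 11. Their biological coefficients of variation were 0.1186 and 0.0669, so counts of the 2 fits are not on 1 scale.

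The control cultures show the course without an inhibitor or added acid or base. Between days 3 and 5, markers of the primitive streak fell and genes of heart muscle, liver and foregut rose. EOMES, a T-box factor of mesendoderm, went from 103 ± 13.9 to 2.46 ± 0.0636 FPKM, and WNT8A, a WNT ligand of the streak, from 29.1 ± 2.68 to 0.08 ± 0.0424. TNNT2, which encodes cardiac troponin T, went from 0.08 ± 0.0424 to 25.7 ± 0.205 FPKM, and MYL7, an atrial myosin light chain, from 4.33 ± 0.0778 to 416 ± 7.13. TTR, a transport protein made by the liver, was at 0 counts on day 3 and at 17.9 ± 1.1 FPKM on day 5, at least 217-fold higher against a floor of 3 counts per library. Of the 12 primitive streak and mesendoderm genes tested, 10 fell and 1 rose (adjusted p = 6.34e-08). All 13 liver and foregut markers tested rose (adjusted p = 6.54e-12), as did 15 of 21 sarcomere genes, with 1 lower (adjusted p = 3.29e-09). All 20 G2/M genes fell (adjusted p = 1.80e-17), among them AURKB, a mitotic kinase, from 47.2 ± 0.177 to 12.2 ± 0.509 FPKM. Of 14 pluripotency factors, 8 fell (adjusted p = 8.12e-05). These 5 counts were the same adjusted over the list alone. Of the 18 liver and foregut markers of the list, 13 passed the filter. A gene silent on day 3 passes it only where another group expresses it, which favours rises. In all, 1793 genes rose and 1338 fell between days 3 and 5.

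Against undifferentiated cells, pluripotency transcripts were lower in the control of day 7 and those of heart and liver higher. POU5F1 (OCT4) went from 754 ± 22.5 to 1 ± 0.163 FPKM, and NANOG from 70.6 ± 4.4 FPKM to 0 counts, at least 1021-fold lower. HAND1, a factor of the early heart and lateral mesoderm (ENSG00000113196, chromosome 5, 153854532 to 153857824 on GRCh37), went from 0.03 ± 0 to 648 ± 2.15 FPKM. APOA2, a plasma apolipoprotein, reached 442 ± 7.3 FPKM from 0 counts. Of 14 pluripotency factors, 13 fell by day 7 (adjusted p = 2.05e-08, and adjusted p = 0.0562 with an estimated correlation), and all 14 had fallen by day 11 (adjusted p = 3.85e-09). Cardiac transcription factors were higher in 14 of 16 cases and lower in 2 on day 7 (adjusted p = 3.03e-08), and all 18 liver and foregut markers were higher (adjusted p = 8.90e-10, and adjusted p = 0.112 with an estimated correlation). On day 11, 21 of 23 sarcomere genes were higher than on day 0 and 1 was lower (adjusted p = 2.29e-09, and adjusted p = 0.199 with an estimated correlation), and 10 of 11 HOX genes were higher (adjusted p = 8.95e-05, and adjusted p = 0.121 with an estimated correlation), among them HOXB6, a positional factor of the trunk, at 8.73 ± 0.283 FPKM from 0 counts. From day 7 to day 11, 16 of 23 sarcomere genes rose (adjusted p = 6.02e-08, and adjusted p = 0.206 with an estimated correlation), with MYH7, a myosin heavy chain, going from 0.335 ± 0.00707 to 3.76 ± 0.0707 FPKM. Liver and foregut markers rose in 12 of 18 cases and fell in 2 (adjusted p = 0.00126, and adjusted p = 0.333 with an estimated correlation), with APOA4 going from 13.2 ± 0.24 to 949 ± 108 FPKM. These 8 counts were the same adjusted over the list alone. Of the 28 HOX genes of the list, 11 passed the filter. A gene silent on day 0 passes it only where a later group expresses it, which favours rises. In all, 3557 genes rose and 2875 fell by day 7, 4210 rose and 3056 fell by day 11, and 1409 rose and 510 fell between days 7 and 11. MYH7 is close to MYH6 in sequence, so the split of reads between the 2 is uncertain.

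**Figure D2:**
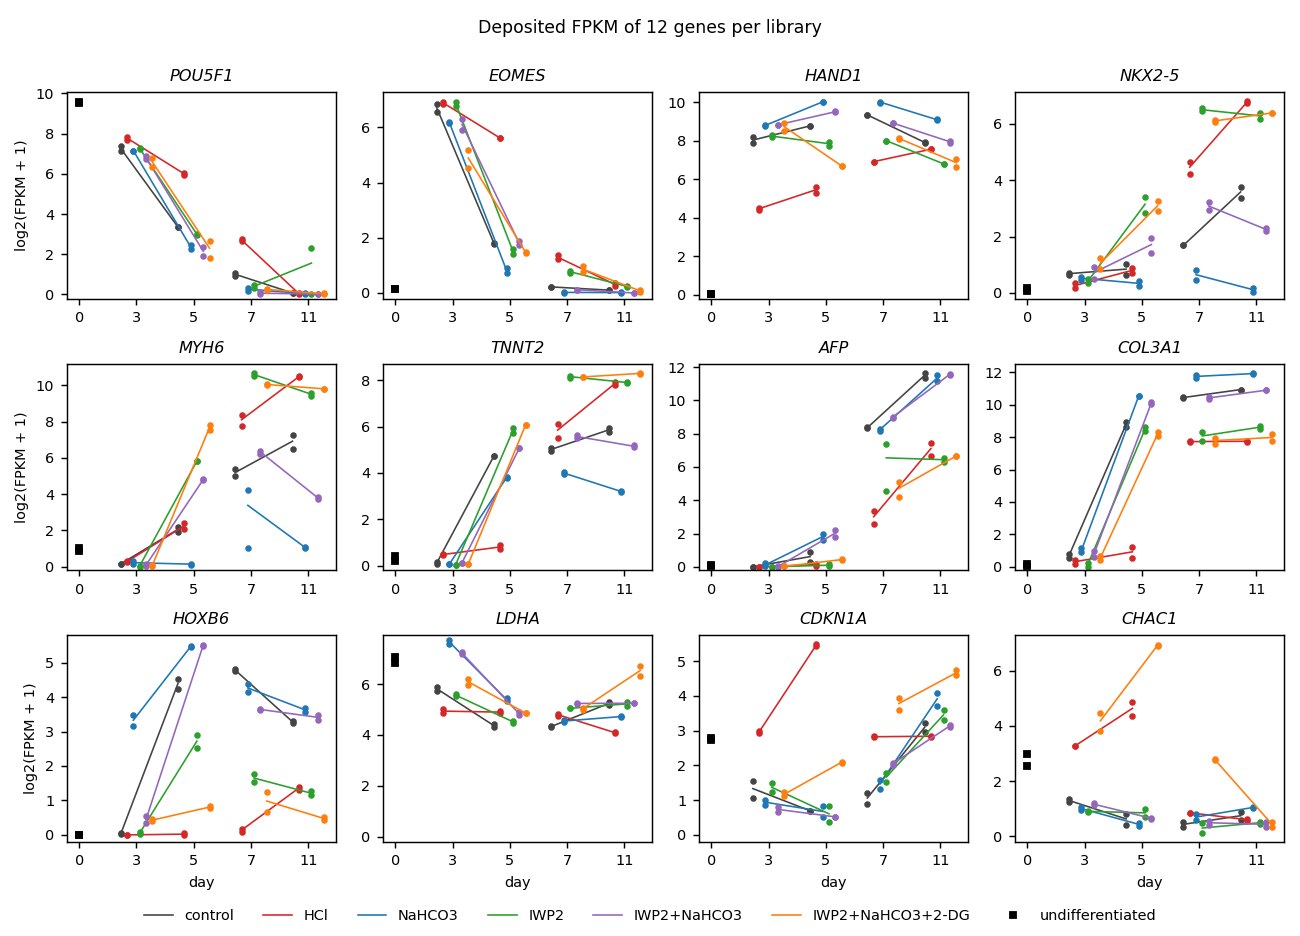
Deposited FPKM of 12 genes as log2(FPKM + 1) against day, 1 point per library, with lines joining the group means of days that share a table and squares for undifferentiated cells. TNNT2 in the control goes from 0.08 ± 0.0424 FPKM on day 3 to 25.7 ± 0.205 on day 5, and with HCl it stands at 0.745 ± 0.163 on day 5.

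IWP2 was compared with the control to see what the WNT inhibitor changes. On day 3, targets of WNT/beta-catenin were lower, and 28 genes rose and 78 fell in all. DKK1, a secreted WNT antagonist that WNT itself induces (ENSG00000107984, chromosome 10, 54074056 to 54077802 on GRCh37), went from 9.63 ± 0.509 FPKM in the control to 0.35 ± 0.226 with IWP2, a log2 fold change of -4.74 (SE 0.34, adjusted p = 1.38e-07). Of 15 WNT/beta-catenin target genes, 7 fell (adjusted p = 3.74e-26). LIPG, an endothelial-type lipase, fell by 2.16 on the log2 scale. The day 3 count of 106 genes became 52 without IWP2 replicate 1, 59 without IWP2 replicate 2 or without control replicate 1, and 77 without control replicate 2. It was 184 with no filter on low values, 49 with the libraries of day 3 alone, 57 with a pseudocount of 0.1 and 163 without the first 2-DG library of day 3.

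On day 5, heart muscle genes were higher with IWP2 and liver genes lower. MYH6, the atrial myosin heavy chain, stood at 55.7 ± 0.375 FPKM against 3.16 ± 0.509 in the control (log2 4.14), and NKX2-5, an early cardiac homeobox factor, at 7.88 ± 2.45 against 0.795 ± 0.346 (log2 3.33). HNF4A, a liver nuclear receptor, stood at 3.01 ± 0.311 against 27.4 ± 2.18 FPKM, and EPCAM, an epithelial adhesion protein, at 11.9 ± 0.0566 against 50.8 ± 5.05. Sarcomere genes rose in 14 of 21 cases and fell in 1 (adjusted p = 1.03e-11), and 12 of 13 liver and foregut markers fell (adjusted p = 9.84e-14). WNT/beta-catenin targets fell in 7 of 15 cases (adjusted p = 3.92e-08), with SP5 at 4.49 ± 0.0707 against 16 ± 1.61 FPKM, and epithelial markers in 7 of 13 (adjusted p = 1.42e-06, and adjusted p = 0.0693 with an estimated correlation). These counts, and that of day 3, were the same adjusted over the list alone. In all, 334 genes rose and 837 fell.

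By day 7 the sarcomere list was raised almost throughout. MYH6 stood at 1552 ± 119 FPKM with IWP2 against 35.7 ± 6.43 in the control, TNNT2 at 284 ± 11.7 against 31.4 ± 1.66, and MYL3, a ventricular light chain, at 260 ± 15.6 against 6.5 ± 1.74. Of 23 sarcomere genes, 22 rose (adjusted p = 4.02e-18, and adjusted p = 0.147 with an estimated correlation). Genes of the TCA cycle and fatty acid oxidation rose in 18 of 25 cases (adjusted p = 1.83e-18), with PPARGC1A, a coactivator of mitochondrial genes, at 18.9 ± 1.18 against 1.34 ± 0.0636 FPKM. Nuclear oxidative phosphorylation genes rose in 20 of 25 cases (adjusted p = 2.73e-17, and adjusted p = 0.157 with an estimated correlation), among them CYCS, cytochrome c, at 136 ± 11 against 27.4 ± 1.02. Fibroblast and matrix genes fell in 12 of 15 cases (adjusted p = 1.86e-10, and adjusted p = 0.17 with an estimated correlation), with LUM, a matrix proteoglycan, at 47 ± 18.8 against 573 ± 19.4. One IWP2 library of day 7 had higher liver transcripts than the other, with AFP at 92.3 ± 99.1 FPKM, and the fall of AFP against the control, -1.73 on the log2 scale, lost its call with no filter, with the libraries of day 7 alone and without IWP2 replicate 1 (-0.92), control replicate 1 (-1.777) or control replicate 2 (-1.688), and became -3.78 without IWP2 replicate 2. In all, 1568 genes rose and 1466 fell.

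On day 11, all 18 liver and foregut markers tested were lower with IWP2 (adjusted p = 6.08e-15, and adjusted p = 0.153 with an estimated correlation). APOA4 stood at 8.69 ± 2.89 FPKM against 949 ± 108, and AFP at 85.5 ± 9.55 against 2897 ± 370. Sarcomere genes rose in 22 of 23 cases (adjusted p = 1.19e-14, and adjusted p = 0.153 with an estimated correlation), with MYH7 at 39.5 ± 0.099 against 3.76 ± 0.0707, and TCA cycle and fatty acid oxidation genes in 13 of 25 (adjusted p = 6.08e-15), with FABP3, a heart fatty acid carrier, at 118 ± 2.26 against 27.2 ± 3.09. HOX genes fell in 9 of 11 cases (adjusted p = 8.36e-05, and adjusted p = 0.153 with an estimated correlation), with HOXB6 at 1.31 ± 0.141 against 8.73 ± 0.283. The 8 counts of days 7 and 11 were the same adjusted over the list alone. Mitochondrially encoded genes held 7.54% and 7.85% of the counts of the IWP2 libraries and 3.81% and 3.95% of the control's. In all, 1151 genes rose and 1602 fell, and the IWP2 effect differed between days 3 and 5 for 782 genes and between days 7 and 11 for 1068.

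**Figure D3:**
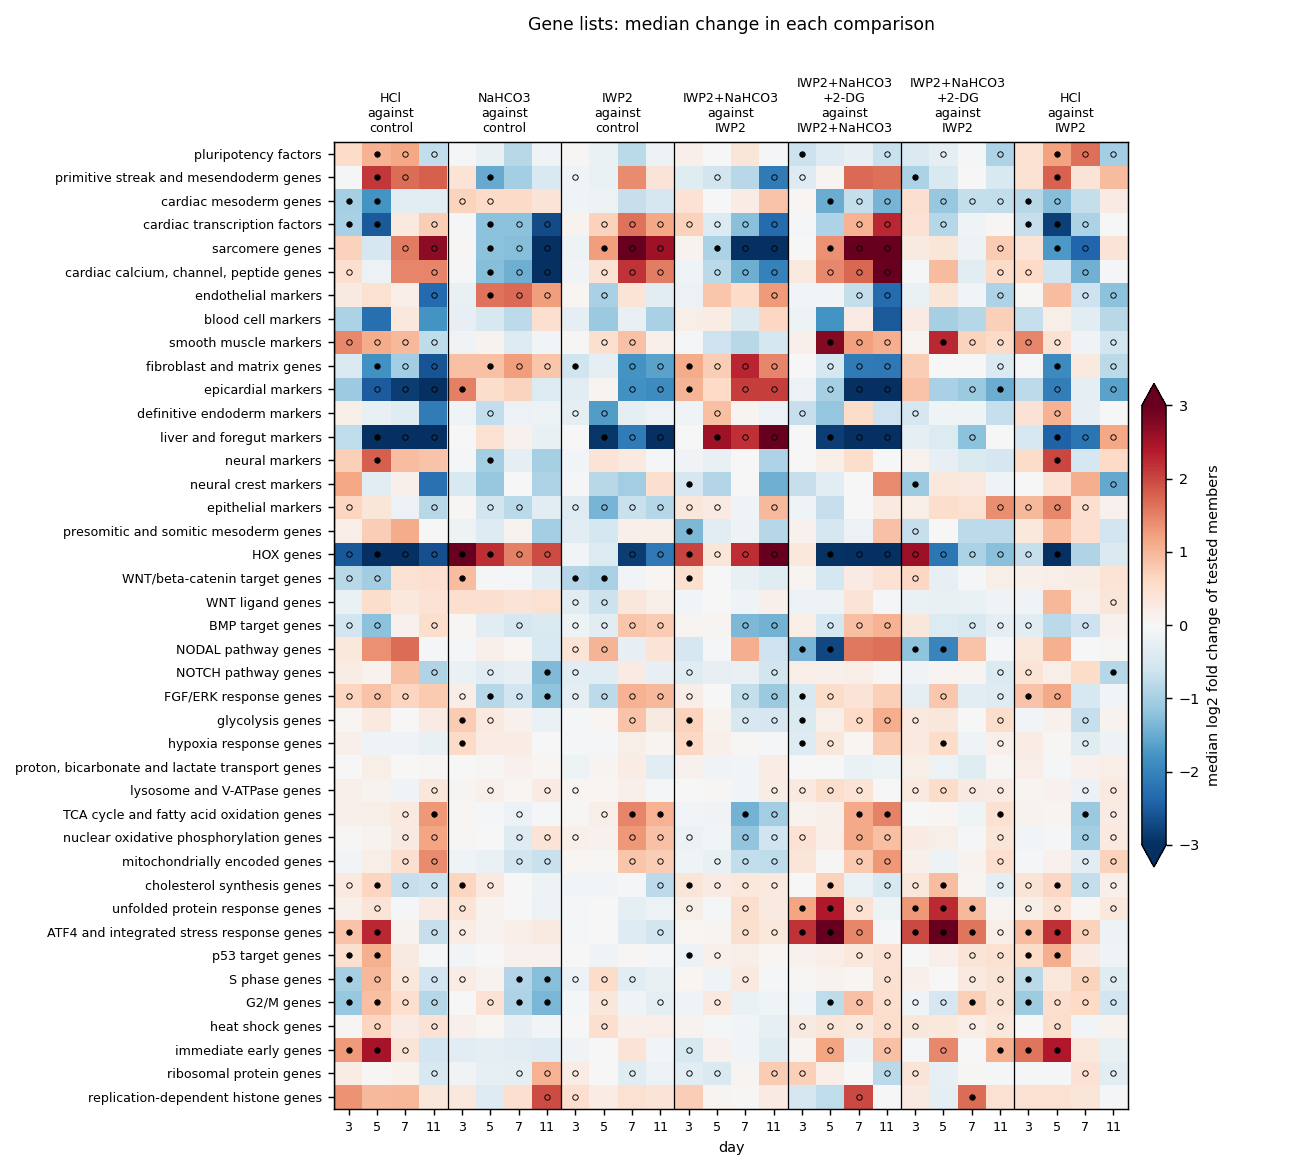
Median log2 fold change of the tested members of 41 gene lists (rows) in 7 comparisons on 4 days (columns), from -3 in blue to 3 in red. Filled circles mark lists called with the preset and with an estimated correlation, open circles those called with the preset correlation alone, so that the TCA cycle and fatty acid oxidation list reads 1.47 for IWP2 against control on day 7 with a filled circle.

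HCl was compared with the control for the effect of added acid without the inhibitor. On day 3, stress genes were higher and mitotic and cardiac mesoderm genes lower. GDF15, a stress cytokine and p53 target (ENSG00000130513, chromosome 19, 18485541 to 18499986 on GRCh37), stood at 12.8 ± 0.276 FPKM against 0.41 ± 0.0424 in the control, a log2 fold change of 5.02 (SE 0.31, adjusted p = 6.96e-10). ATF3, a stress transcription factor, stood at 9.72 ± 0.113 against 1.54 ± 0.12, CYR61, an immediate early matrix protein, at 112 ± 3.84 against 5.47 ± 1.34, and HAND1 at 21.1 ± 0.912 against 261 ± 41.5. LGR5, a receptor of the WNT-enhancing R-spondins, fell by 5.95 on the log2 scale. Integrated stress response genes rose in 6 of 19 cases (adjusted p = 7.87e-09), immediate early genes in 6 of 10 (adjusted p = 8.91e-09) and p53 targets in 5 of 18 (adjusted p = 4.74e-06). G2/M genes fell in 14 of 20 cases (adjusted p = 2.56e-18), with MKI67 at 9.04 ± 0.205 against 29.1 ± 0.735 FPKM, and cardiac mesoderm genes in 5 of 10 (adjusted p = 4.42e-07). In all, 1026 genes rose and 807 fell. The largest rises, of RPPH1 and RNA18S5, rest on 1 library: RPPH1 had 75 CPM (counts per 1e+06 counts) in HCl replicate 1 and 1.33 in replicate 2.

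On day 5, HCl cultures had more streak and pluripotency transcripts than the control and fewer cardiac and liver transcripts. EOMES stood at 47.7 ± 0.0424 FPKM against 2.46 ± 0.0636, and TDGF1, a NODAL co-receptor of pluripotent cells, at 61.1 ± 0.219 against 4.07 ± 0.481. HAND2, a cardiac factor, stood at 0.845 ± 0.191 against 58.7 ± 7.67, TNNT2 at 0.745 ± 0.163 against 25.7 ± 0.205, and APOA1 at 1.92 ± 0.0566 against 198 ± 26.1. CDKN1A (p21), a cell cycle inhibitor and p53 target, stood at 43.2 ± 0.87 against 0.615 ± 0.00707, a log2 fold change of 6.16 (SE 0.29). Primitive streak genes rose in 7 of 12 cases and fell in 2 (adjusted p = 0.00257), pluripotency factors rose in 7 of 14 and fell in 1 (adjusted p = 7.54e-04), and neural markers rose in 5 of 8 and fell in 1 (adjusted p = 0.00106), with SOX3 at 10.2 ± 1.57 against 0.26 ± 0.0283 FPKM. Cardiac transcription factors fell in 10 of 16 cases (adjusted p = 4.52e-08) and liver and foregut markers in 12 of 13 (adjusted p = 2.32e-09). Integrated stress response genes rose in 16 of 19 cases (adjusted p = 1.29e-13), with TRIB3 at 18.1 ± 2.75 against 0.665 ± 0.0495, and p53 targets in 10 of 18, with 1 lower (adjusted p = 2.93e-07). The 12 counts of days 3 and 5 were the same adjusted over the list alone. In all, 1701 genes rose and 1755 fell, and the HCl effect differed between days 3 and 5 for 2841 genes by the interaction test.

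On day 7, HCl cultures had more sarcomere transcripts than the control and fewer liver transcripts. UNC45B, a myosin chaperone, stood at 62.6 ± 7.76 FPKM against 4.67 ± 0.424, and LDB3, a Z-disc protein, at 10 ± 1.91 against 1.21 ± 0.0212. RBP4, the plasma retinol carrier, stood at 2.5 ± 0.389 against 140 ± 3.84, and HOXB6 at 0.1 ± 0.0424 against 26.5 ± 0.707. Sarcomere genes rose in 19 of 23 cases (adjusted p = 8.46e-09, and adjusted p = 0.3 with an estimated correlation). Liver and foregut markers fell in 14 of 18 cases, and in 15 adjusted over the list alone (adjusted p = 3.57e-12, and adjusted p = 0.208 with an estimated correlation). Pluripotency factors rose in 6 of 14 cases (adjusted p = 0.00212, and adjusted p = 0.317 with an estimated correlation), with SOX2 at 1.84 ± 0.0566 against 0.16 ± 0.0283. The calls of POU5F1 and MYH6, at 5.54 ± 0.339 and 275 ± 77.8 FPKM with HCl, ended under some alternatives. POU5F1 had an adjusted p of 0.14 with DESeq2 and 0.0616 with limma and a pseudocount of 0.1 (1.81e-07 to 0.14 over its alternatives). Its call also ended without control replicate 1, at a log2 fold change of 2.348. MYH6 had an adjusted p of 0.0556 in edgeR with the libraries of day 7 alone (3.34e-07 to 0.0556). In all, 1173 genes rose and 1468 fell.

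On day 11, heart muscle and mitochondrial transcripts were higher with HCl and liver, matrix and endothelial transcripts lower. MYH6 stood at 1432 ± 40.3 FPKM against 120 ± 45, MYL3 at 660 ± 4.44 against 43 ± 6.76, and NKX2-5 at 108 ± 2.84 against 11 ± 2.28. COL3A1, a fibrillar collagen, stood at 213 ± 5.73 against 1945 ± 1.24, AHSG, a liver glycoprotein, at 14.4 ± 5.31 against 491 ± 50.9, and CDH5, the endothelial cadherin, at 0.215 ± 0.0354 against 1.48 ± 0. Sarcomere genes rose in 21 of 23 cases (adjusted p = 6.58e-12, and adjusted p = 0.129 with an estimated correlation). All 13 mitochondrially encoded genes tested rose (adjusted p = 7.32e-11, and adjusted p = 0.129 with an estimated correlation), and 19 of 25 nuclear oxidative phosphorylation genes (adjusted p = 2.31e-14, and adjusted p = 0.129 with an estimated correlation). Their share of all counts was 9.87% and 9.75% for the mitochondrially encoded genes in the HCl libraries and 3.81% and 3.95% in the control. All 18 liver and foregut markers fell (adjusted p = 4.76e-09, and adjusted p = 0.129 with an estimated correlation), as did 14 of 15 fibroblast and matrix genes (adjusted p = 6.74e-10, and adjusted p = 0.129 with an estimated correlation) and 7 of 11 endothelial markers (adjusted p = 9.16e-04, and adjusted p = 0.129 with an estimated correlation). These counts, and those of sarcomere genes and pluripotency factors on day 7, were the same adjusted over the list alone. In all, 1545 genes rose and 2349 fell, and the HCl effect differed between days 7 and 11 for 3151 genes.

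**Figure D4:**
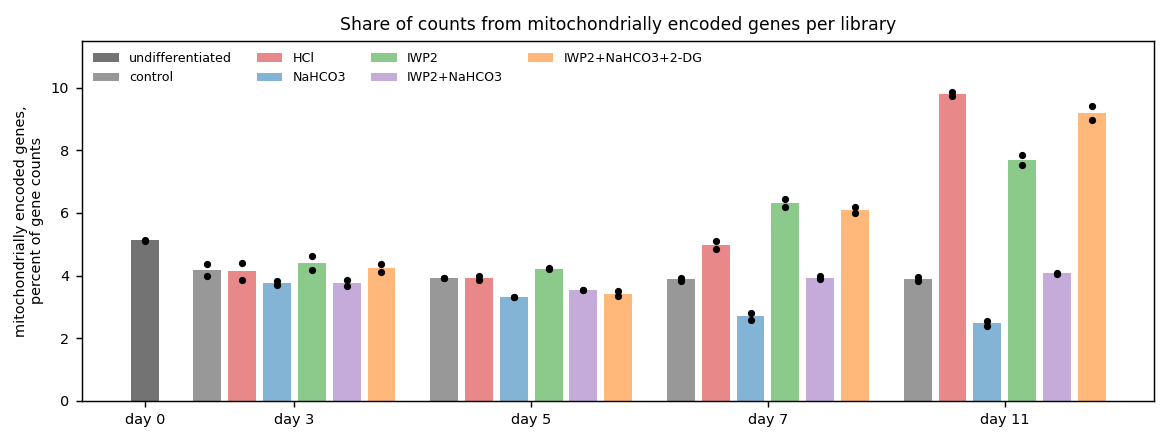
Percent of gene counts from mitochondrially encoded genes in each treatment and day, with bars for the mean of 2 libraries and points for each library. On day 11 the HCl libraries stand at 9.87% and 9.75% and the control libraries at 3.81% and 3.95%.

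NaHCO3 was compared with the control for the effect of added base without the inhibitor. On day 3, glycolytic genes, WNT targets and HOX genes were higher. LDHA, lactate dehydrogenase A, stood at 200 ± 16.7 FPKM against 55.4 ± 4.16 (log2 1.91, SE 0.12), and SLC2A1, a glucose transporter, at 56.4 ± 1.85 against 15.5 ± 0.693. CDX2, a caudal homeobox factor and WNT target (ENSG00000165556, chromosome 13, 28536274 to 28545276 on GRCh37), stood at 13.9 ± 0.219 against 0.75 ± 0.311, and HOXB6 at 9.04 ± 1.59 against 0.02 ± 0.0141. LEFTY2, an inhibitor of NODAL, fell by 4.47 on the log2 scale. Glycolysis genes rose in 7 of 20 cases (adjusted p = 1.77e-16), hypoxia response genes in 6 of 18 (adjusted p = 2.17e-07), with KDM3A, a histone demethylase, at 7.41 ± 0.778 against 3.19 ± 0.163, WNT/beta-catenin targets in 7 of 15 (adjusted p = 1.10e-12) and HOX genes in 9 of 12 (adjusted p = 1.68e-13). In all, 395 genes rose and 311 fell.

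On day 5, sarcomere and FGF response genes were lower with NaHCO3 and matrix and HOX genes higher. MYH6 stood at 0.095 ± 0.0354 FPKM against 3.16 ± 0.509, and UNC45B at 0.035 ± 0.0354 against 7.94 ± 1.13. DUSP6, a phosphatase that FGF signalling induces, stood at 3.27 ± 0.679 against 62.4 ± 5.09, POSTN, a matrix protein, at 21.9 ± 2.16 against 0.315 ± 0.106, and HOXB8 at 24.8 ± 0.198 against 0.37 ± 0.0849. Sarcomere genes fell in 11 of 21 cases, in 12 adjusted over the list alone, and rose in 1 by either count (adjusted p = 8.99e-08). FGF/ERK response genes fell in 5 of 13 cases (adjusted p = 1.71e-09). Fibroblast and matrix genes rose in 7 of 15 cases (adjusted p = 1.62e-08), and HOX genes rose in 7 of 12 and fell in 1 (adjusted p = 4.46e-08). The 4 counts of day 3 and the last 3 of day 5 were the same adjusted over the list alone. In all, 470 genes rose and 635 fell.

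On days 7 and 11, heart muscle transcripts were lower than in the control with NaHCO3. On day 7, MYL7 stood at 27.5 ± 12.7 FPKM against 304 ± 26.5, NKX2-5 at 0.565 ± 0.247 against 2.23 ± 0.00707, and the endothelial cadherin CDH5 at 4.9 ± 1.2 against 0.55 ± 0.17. On day 11, MYH6 stood at 1.07 ± 0.106 against 120 ± 45, NKX2-5 at 0.08 ± 0.0707 against 11 ± 2.28, MKI67 at 1.93 ± 0.00707 against 9.14 ± 0.332, and JAG1, a NOTCH ligand, at 7.26 ± 0.148 against 29.4 ± 0.629. Sarcomere genes fell in 11 of 23 cases on day 7, in 12 adjusted over the list alone (adjusted p = 3.21e-08, and adjusted p = 0.295 with an estimated correlation), and in 20 of 23 on day 11 (adjusted p = 2.57e-13, and adjusted p = 0.163 with an estimated correlation). Endothelial markers rose in 8 of 11 cases on day 7 (adjusted p = 1.26e-06, and adjusted p = 0.0561 with an estimated correlation). G2/M genes fell in 7 of 20 cases on day 7 (adjusted p = 2.10e-17) and in 18 on day 11 (adjusted p = 5.91e-16), S phase genes in 14 of 18 on day 11 (adjusted p = 3.14e-10), NOTCH pathway genes in 8 of 10 (adjusted p = 2.65e-04) and FGF/ERK response genes in 7 of 13 (adjusted p = 3.33e-07). The counts other than that of sarcomere genes on day 7 were the same adjusted over the list alone. In all, 937 genes rose and 951 fell on day 7, and 1237 rose and 1875 fell on day 11. Replicate 2 of NaHCO3 on day 7 held 1200 CPM of RNA28S5 and replicate 1 held 385. The 2 libraries also differed in MYH6. Its NaHCO3 effect beside IWP2 minus that without IWP2, tested below, was -2.558 on the log2 scale on day 7. That difference became 0.612 without NaHCO3 replicate 1 and -3.478 without NaHCO3 replicate 2. The effect differed between days 3 and 5 for 1035 genes and between days 7 and 11 for 2105. With a pseudocount of 0.1 on the FPKM the splits were 719 higher and 1152 lower on day 7, and 824 and 2328 on day 11.

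IWP2 with NaHCO3 was compared with IWP2 alone for the effect of base during inhibitor-driven differentiation. On day 3, glycolysis and hypoxia genes were higher and somitic genes lower. LDHA stood at 148 ± 6.21 FPKM against 46.4 ± 2.06, SLC2A1 at 39.2 ± 5.63 against 12.2 ± 0.346, and DLL3, a NOTCH ligand of the presomitic mesoderm, at 34.1 ± 2.8 against 126 ± 13.3. IGF2, a fetal growth factor, rose by 3.17 on the log2 scale. Glycolysis genes rose in 5 of 20 cases (adjusted p = 4.69e-17) and hypoxia response genes in 4 of 18 (adjusted p = 2.38e-11), and presomitic and somitic genes fell in 5 of 11 (adjusted p = 4.37e-06). In all, 329 genes rose and 223 fell, and the total of 552 became 339 without replicate 1 of IWP2 with NaHCO3. Replicate 2 of that group held 2870 CPM of RNA28S5, a ribosomal RNA gene, and replicate 1 held 281.

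From day 5 on, base in the presence of IWP2 lowered heart muscle genes and raised liver genes. On day 5, APOA2 stood at 49.9 ± 5.66 FPKM against 5.27 ± 0.0141 with IWP2 alone, and UNC45B at 8.4 ± 0.856 against 31.5 ± 1.51. On day 7, MYH6 stood at 79.3 ± 6.63 against 1552 ± 119, TNNT2 at 46.7 ± 2.35 against 284 ± 11.7, and LUM at 523 ± 9.21 against 47 ± 18.8. On day 11, MYH6 stood at 12.9 ± 0.87 against 729 ± 62.5, NKX2-5 at 3.78 ± 0.255 against 77.1 ± 7, PLN, a regulator of the calcium pump, at 25.1 ± 0.12 against 227 ± 2.95, and APOA4 at 530 ± 61.4 against 8.69 ± 2.89. Sarcomere genes fell in 7 of 21 cases on day 5, in 9 adjusted over the list alone (adjusted p = 3.47e-07), in 22 of 23 on day 7 (adjusted p = 9.60e-15, and adjusted p = 0.144 with an estimated correlation) and in 22 on day 11, 23 adjusted over the list alone (adjusted p = 1.12e-14, and adjusted p = 0.14 with an estimated correlation). Liver and foregut markers rose in 11 of 13 cases on day 5, in 12 adjusted over the list alone, with 1 lower (adjusted p = 9.37e-14), in 12 of 18 on day 7 (adjusted p = 3.13e-07, and adjusted p = 0.204 with an estimated correlation) and in 16 on day 11 (adjusted p = 2.67e-09, and adjusted p = 0.144 with an estimated correlation). TCA cycle and fatty acid oxidation genes fell in 18 of 25 cases on day 7 (adjusted p = 9.55e-18), and fibroblast and matrix genes rose in 13 of 15 (adjusted p = 9.06e-13, and adjusted p = 0.144 with an estimated correlation). On day 11, 14 of 15 cardiac calcium handling, channel and peptide genes fell (adjusted p = 3.37e-09, and adjusted p = 0.0768 with an estimated correlation) and all 11 HOX genes rose (adjusted p = 3.47e-06, and adjusted p = 0.115 with an estimated correlation), with HOXB8 at 5.86 ± 1.07 against 0.295 ± 0.262. The counts given once were the same adjusted over the list alone. In all, 630 genes rose and 375 fell on day 5, 1549 and 1530 on day 7, and 1809 and 1606 on day 11. The effect differed between days 3 and 5 for 958 genes and between days 7 and 11 for 1398.

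Whether base acted differently with and without IWP2 was tested as an interaction, positive where the change with NaHCO3 was higher beside IWP2. On day 3 it called 27 genes higher and 42 lower. WNT/beta-catenin targets were lower in 4 of 15 cases, in 5 adjusted over the list alone (adjusted p = 8.60e-05); they were CDX2, NKD1, APCDD1 and AXIN2, whose calls ended in 5, 10, 7 and 6 of the alternatives. On day 5, liver and foregut markers were higher in 10 of 13 cases, 12 adjusted over the list alone (adjusted p = 1.69e-13), epithelial markers in 7 of 13, 8 adjusted over the list alone (adjusted p = 6.93e-12), and FGF/ERK response genes in 6 of 13 by either count (adjusted p = 6.84e-17), with DUSP6 at 3.20 on the log2 scale. On day 7, S phase genes were higher in 13 of 18 cases by either count (adjusted p = 2.40e-12), and TCA cycle and fatty acid oxidation genes were lower in 13 of 25, 14 adjusted over the list alone (adjusted p = 1.76e-13), with IDH3A, a TCA cycle enzyme, at -2.09. On day 11, G2/M genes were higher in 16 of 20 cases (adjusted p = 3.26e-14), S phase genes in 12 of 18 (adjusted p = 4.86e-09) and all 18 liver and foregut markers (adjusted p = 3.17e-11, and adjusted p = 0.153 with an estimated correlation), each by either count. CDC45, a replication factor, stood at 2.70 and FGA, fibrinogen alpha, at 6.06. The interaction called 551 genes higher and 130 lower on day 5, 1449 and 1251 on day 7, and 2170 and 1168 on day 11. The day 3 total of 69 became 24 and 49 without control replicate 1 and 2, 29 and 32 without NaHCO3 replicate 1 and 2, 25 and 33 without IWP2 replicate 1 and 2, and 27 and 28 without replicate 1 and 2 of IWP2 with NaHCO3. It was 175 with no filter, 111 with DESeq2, 14 with the libraries of day 3 alone and 191 without the first 2-DG library of day 3. Its split of higher and lower was 95 and 80 with no filter, 101 and 90 without that 2-DG library, 4 and 10 with day 3 alone, and 19 and 55 with limma on log2(FPKM + 1). On day 7 a pseudocount of 0.1 gave 1804 higher and 1022 lower.

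2-DG was added to IWP2 and NaHCO3, and the comparison with IWP2 and NaHCO3 gives its effect. On days 3 and 5, genes of the integrated stress and unfolded protein responses were higher. CHAC1, an ATF4 target that degrades glutathione (ENSG00000128965, chromosome 15, 41245160 to 41248710 on GRCh37), stood at 17.2 ± 5.54 FPKM against 1.24 ± 0.0636 on day 3 and at 121 ± 2.35 against 0.57 ± 0.0424 on day 5, log2 fold changes of 3.95 (SE 0.28) and 7.89 (SE 0.31). HSPA5 (BiP), the chaperone of the endoplasmic reticulum, stood at 600 ± 0.834 against 206 ± 5.77 on day 3. HK2, a hexokinase, stood at 7.08 ± 2.65 against 24.2 ± 0.297 on day 3, and CER1, a NODAL antagonist, at 2.78 ± 0.339 against 25 ± 3.09. Integrated stress response genes rose in 17 of 19 cases on day 3 (adjusted p = 1.38e-35) and in 17 on day 5 (adjusted p = 2.75e-25), and unfolded protein response genes in 12 of 18 on day 3 (adjusted p = 6.54e-26) and in 17 on day 5 (adjusted p = 8.95e-21). On day 3, NODAL pathway genes fell in 4 of 6 cases (adjusted p = 2.41e-05, and 0.0653 without replicate 2 of the 2-DG group, the highest of its alternatives, of which the lowest is 6.55e-08) and glycolysis genes in 3 of 20 (adjusted p = 1.34e-08). In all, 259 genes rose and 361 fell on day 3. The 2 libraries with 2-DG of day 3 differed over 2-fold in 2985 genes, where the other 11 pairs of the table differed in 605 to 979, and without replicate 2 the comparison called 2427 genes.

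On day 5, smooth muscle and sarcomere genes were higher with 2-DG and liver genes lower. TAGLN, an actin-binding protein of smooth muscle and early heart, stood at 670 ± 29.2 FPKM against 16.7 ± 0.488, MYH6 at 204 ± 27.8 against 26.8 ± 0.438, CSRP3, a muscle LIM protein, at 33.6 ± 1.39 against 0.185 ± 0.134, and TTR at 0.86 ± 0.099 against 21 ± 1.09. Smooth muscle markers rose in 7 of 8 cases (adjusted p = 1.91e-05) and sarcomere genes in 12 of 21 (adjusted p = 5.53e-05), and liver and foregut markers fell in 12 of 13 (adjusted p = 3.10e-08). In all, 1217 genes rose and 1628 fell. With a pseudocount of 0.1 the splits were 151 higher and 549 lower on day 3, and 939 and 1986 on day 5; limma on log2(FPKM + 1) gave 70 and 184 on day 3, and the fit on day 3 alone called 368 genes.

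On days 7 and 11, 2-DG beside IWP2 and base raised heart muscle genes and lowered liver genes, and on day 11 HOX genes were lower. MYH6 stood at 1063 ± 22.1 FPKM against 79.3 ± 6.63 on day 7 and at 900 ± 14.8 against 12.9 ± 0.87 on day 11, and NKX2-5 at 83 ± 0.827 against 3.78 ± 0.255. APOC3, an apolipoprotein, stood at 1.67 ± 0.389 against 213 ± 6.39, HOXB8 at 0.035 ± 0.0495 against 5.86 ± 1.07, and TBX18, a factor of the epicardium and sinus region, at 0.5 ± 0.17 against 42.3 ± 2.79. Sarcomere genes rose in 22 of 23 cases on day 7 (adjusted p = 4.94e-14, and adjusted p = 0.0977 with an estimated correlation) and all 23 on day 11 (adjusted p = 1.08e-16, and adjusted p = 0.0966 with an estimated correlation). TCA cycle and fatty acid oxidation genes rose in 15 of 25 cases on day 7 (adjusted p = 9.16e-16), with FABP3 at 133 ± 6.33 against 19.2 ± 0.389, and integrated stress response genes in 12 of 19 (adjusted p = 1.28e-07, and adjusted p = 0.0972 with an estimated correlation). Liver and foregut markers fell in 15 of 18 cases on day 7 (adjusted p = 2.16e-10, and adjusted p = 0.0977 with an estimated correlation) and in 16 on day 11 (adjusted p = 3.52e-08, and adjusted p = 0.147 with an estimated correlation). On day 11, all 11 HOX genes fell (adjusted p = 5.18e-07, and adjusted p = 0.0922 with an estimated correlation), epicardial markers fell in 7 of 8 cases and rose in 1 (adjusted p = 5.28e-05, and adjusted p = 0.105 with an estimated correlation), and 11 of 13 mitochondrially encoded genes rose (adjusted p = 1.88e-09, and adjusted p = 0.0966 with an estimated correlation). The counts of these 4 days were the same adjusted over the list alone. In all, 1310 genes rose and 1703 fell on day 7, and 1719 rose and 2172 fell on day 11. The effect differed between days 3 and 5 for 1980 genes, 3147 without replicate 2 of the 2-DG group of day 3, and between days 7 and 11 for 1778. Of the genes called for base beside IWP2, 61 of 552 were called the opposite way with 2-DG on day 3, 578 of 1005 on day 5, 2015 of 3079 on day 7 and 2686 of 3415 on day 11, and 30, 77, 21 and 10 the same way. Both comparisons use the libraries of IWP2 with NaHCO3, so their errors push such genes to opposite sides. Against IWP2 alone, 380, 300, 440 and 235 of them were called in the direction of base, and those 2 comparisons share the IWP2 libraries, whose errors push such genes to the same side. With no true change, 10 simulated draws called at most 1 gene for either step on a day and 0 in these overlaps, too few to show what the sharing adds beside real effects.

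IWP2 with NaHCO3 and 2-DG was also compared with IWP2 alone, for what remained different from the inhibitor. Stress response genes were higher on days 3 to 7, and on day 11 the cultures differed in epicardial and muscle genes. STC2, a secreted glycoprotein and ATF4 target, stood at 7.75 ± 1.32 FPKM against 0.51 ± 0.184 on day 3, HERPUD1, a protein of endoplasmic reticulum degradation, at 83.1 ± 7.46 against 5.24 ± 0.0707 on day 5, and TRIB3 at 8.25 ± 1.05 against 0.69 ± 0.113 on day 7. On day 11, TBX18 stood at 0.5 ± 0.17 against 27.3 ± 6.22, MYL2, a ventricular light chain, at 6.04 ± 0.813 against 0.34 ± 0.0566, MYH7 at 347 ± 43.2 against 39.5 ± 0.099, and MYH6 at 900 ± 14.8 against 729 ± 62.5 with no call. Integrated stress response genes rose in 16 of 19 cases on day 3 (adjusted p = 4.98e-27) and 13 on day 7 (adjusted p = 1.38e-21), all 18 unfolded protein response genes rose on day 5 (adjusted p = 9.65e-21), and cholesterol synthesis genes rose in 11 of 24 cases on day 5 (adjusted p = 6.32e-09). On day 11, epicardial markers fell in 6 of 8 cases (adjusted p = 5.55e-09), immediate early genes rose in 6 of 10 (adjusted p = 1.12e-07), epithelial markers in 7 of 13 (adjusted p = 2.15e-09, and adjusted p = 0.0657 with an estimated correlation) and sarcomere genes in 7 of 23, or 8 adjusted over the list alone (adjusted p = 1.80e-08, and adjusted p = 0.172 with an estimated correlation). The other counts were the same adjusted over the list alone. In all, 597 genes rose and 709 fell on day 3, 1234 and 1556 on day 5, 418 and 849 on day 7, and 368 and 701 on day 11. On day 3 the total of 1306 became 2537 without replicate 2 of the 2-DG group, and the splits were 395 higher and 980 lower with a pseudocount of 0.1, and 186 and 371 with limma on log2(FPKM + 1).

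HCl was compared with IWP2 to see whether acid and the inhibitor left the cells in different states. On day 3, mitotic genes were lower with HCl and stress genes higher, and on day 5 cardiac genes were lower and streak genes higher. MKI67 stood at 9.04 ± 0.205 FPKM with HCl against 24.5 ± 2.13 with IWP2 on day 3, and ATF3 at 9.72 ± 0.113 against 1.21 ± 0.0283. MEF2C, a cardiac MADS-box factor, stood at 0.115 ± 0.00707 against 18.2 ± 2.38 on day 5, TNNT2 at 0.745 ± 0.163 against 56.3 ± 6.38, and EOMES at 47.7 ± 0.0424 against 1.86 ± 0.255. G2/M genes were lower with HCl in 13 of 20 cases on day 3 (adjusted p = 1.36e-17) and integrated stress response genes higher in 8 of 19 (adjusted p = 1.17e-09). On day 5, cardiac transcription factors were lower in 13 of 16 cases (adjusted p = 4.71e-09), sarcomere genes lower in 13 of 21 and higher in 1 (adjusted p = 1.40e-06), and primitive streak genes higher in 8 of 12 and lower in 1 (adjusted p = 5.31e-04). On day 7, sarcomere genes were lower in 19 of 23 cases, 20 adjusted over the list alone, and higher in 1 (adjusted p = 9.10e-11, and adjusted p = 0.193 with an estimated correlation). TCA cycle and fatty acid oxidation genes were lower in 16 of 25 and higher in 2 (adjusted p = 1.19e-15). TBX5, a factor of the left heart, stood at 0.58 ± 0.693 against 18.6 ± 0.276, a log2 difference of -5.11. That difference became -7.68 without HCl replicate 2 and -4.158 without HCl replicate 1. By day 11, MYH6 stood at 1432 ± 40.3 against 729 ± 62.5, a log2 difference of 1.03 (SE 0.65) that was not called. NOTCH pathway genes were lower in 5 of 10 cases on day 11 (adjusted p = 4.38e-05), with HEY1 at 2.46 ± 0.0424 against 9.07 ± 1.34, and endothelial markers in 6 of 11, 7 adjusted over the list alone (adjusted p = 6.01e-05, and adjusted p = 0.0798 with an estimated correlation), with CDH5 at 0.215 ± 0.0354 against 1.58 ± 0.283. NPPA, the atrial natriuretic peptide, was lower by 5.03 on the log2 scale. The counts given once were the same adjusted over the list alone. In all, 1163 genes were higher with HCl and 708 lower on day 3, 2004 and 1672 on day 5, 961 and 1462 on day 7, and 408 and 803 on day 11.

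The changes with HCl and with IWP2, each against the control, shared many genes by day 11. MYH7 and NKX2-5 rose in both on that day, and AFP and COL3A1 fell in both. Called higher in both were 8 genes on day 3 where the product of the counts over all genes tested gives 1.7, 85 on day 5 for 32.9, 566 on day 7 for 99.7 and 885 on day 11 for 96.4. Called lower in both were 39 genes for 3.6, 363 for 85, 887 for 116.6 and 1356 for 204. Called in opposite directions were 5, 289, 67 and 20 genes. Across genes, which are not independent replicates, the correlation of the 2 sets of log2 changes was 0.222 on day 3, 0.173 on day 5, 0.622 on day 7 and 0.832 on day 11. The 2 control libraries of a day enter both changes and were not split between them, which would leave 1 for each, whereas the product of counts holds for independent comparisons, so part of the excess over it may come from the shared controls. With no true change, 10 simulated draws called at most 2 genes for HCl and 1 for IWP2 on a day and 0 in both, too few to show how much the shared controls add beside real effects. Counts simulated in this way gave mean correlations of 0.478, 0.492, 0.486 and 0.481 over 100 draws from that sharing alone. The covariance was 0.061, 0.136, 0.548 and 0.829 on the 4 days, and 0.042, 0.043, 0.032 and 0.031 in the simulation. The day 3 correlation reached 0.335 without control replicate 2. By mean log CPM, the group nearest to HCl on day 11 was IWP2 (correlation across genes 0.9821), the group nearest to IWP2 with NaHCO3 and 2-DG was IWP2 (0.984), and the group nearest to IWP2 with NaHCO3 was the control (0.9858).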

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

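Of the tests weighed below, 4 were chosen only after the result was seen: the unequal response to 2-DG, the joint trend on length and GC content, and both on mitochondrial RNA. Where an effect is said to have differed in a number of genes, the difference of effects was itself tested, with edgeR and a Benjamini-Hochberg adjustment.

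The effect of NaHCO3 differed with and without IWP2 in 69 genes on day 3 (27 higher with IWP2, 42 lower), 681 on day 5 (551 and 130), 2700 on day 7 (1449 and 1251) and 3338 on day 11 (2170 and 1168). Between days 3 and 5, the effect against control differed in 2841 genes for HCl (1443 higher on day 5, 1398 lower), 1035 for NaHCO3 (394 and 641) and 782 for IWP2 (261 and 521). Between the same days, the effect of NaHCO3 beside IWP2 differed in 958 genes (477 and 481) and that of 2-DG in 1980 (976 and 1004). Between days 7 and 11, the numbers were 3151 for HCl (1314 higher on day 11, 1837 lower), 2105 for NaHCO3 (876 and 1229), 1068 for IWP2 (234 and 834), 1398 for NaHCO3 beside IWP2 (776 and 622) and 1778 for 2-DG (840 and 938).

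The HCl libraries of day 5 lay between the control of day 3 and that of day 5. The way was taken over 2124 rising and 1594 falling genes. These were at least 2-fold higher or lower in the first control replicate of day 5 than in that of day 3, with no test made. The HCl libraries had covered a median of 0.245 and 0.284 of the way for rising genes and 0.309 and 0.288 for falling genes. The second control replicate of day 5 had covered 0.989 and 0.974. A partial way was not particular to HCl for rising genes: the libraries of IWP2 with NaHCO3 and 2-DG had covered 0.539 and 0.551 (0.991 and 1 for falling genes) and those of IWP2 0.826 and 0.874 (0.967 and 0.984). The larger mean way with HCl, 0.298, restates this pattern. Whether a delayed course with HCl accounts for part or all of the change stays open. Of the 3456 called genes, 1336 (38.7%) lay over 1 log2 unit beyond both controls, off a straight course between them. No control was sampled between days 3 and 5, so a delay alone could give this in genes that peak or dip there. Unequal depth is argued against, since thinning every library to the lowest total moved the mean way by at most 0.015, and a change in the mix of cell types stays open as untested.

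Mitochondrially encoded RNA was high with HCl on day 11, at 9.87% and 9.75% of counts against 3.81% and 3.95% in the control. It was also high on that day with IWP2, NaHCO3 and 2-DG (9.405% and 8.966%) and with IWP2 (7.54% and 7.848%). The share is taken before scaling, so leaving these genes out before scaling, which moved none of 46 counts of genes by over 1.5 times, says nothing of its source. The test set for RNA quality cannot decide whether it played a part. Nuclear oxidative phosphorylation genes had a median log2 change of 1.181 beside 1.414 for the mitochondrially encoded. Such a rise could come with more heart muscle transcripts (sarcomere median 2.691) whatever the RNA quality, and no measure of RNA integrity was examined. A higher content of heart muscle cells is a candidate explanation: the medians of mitochondrially encoded and sarcomere genes had the same sign in 10 of 10 comparisons of days 7 and 11, which share groups: HCl, NaHCO3 and IWP2 against control, NaHCO3 beside IWP2, and 2-DG added to both. In comparisons outside this test, added after its result was seen, the signs agreed for HCl against IWP2 on both days and for IWP2, NaHCO3 and 2-DG against IWP2 on day 11 but not on day 7 (0.115 and -0.157). In the control they agreed from day 7 to day 11, where the share hardly moved (medians of 0.131 and 1.497, shares of 3.88% and 3.882%), and differed from day 0 to day 7 (-0.831 and 5.064) and to day 11 (-0.636 and 7.795), so the share did not follow the sarcomere genes throughout. The form of this test, a count of signs in place of a rank correlation, was settled after the values were seen, and a change of mitochondrial content per cell stays open.

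The 2 libraries of IWP2 with NaHCO3 and 2-DG on day 3 lay over 2-fold apart in 2985 genes, where the other 11 pairs of their table had 605 to 979. A trend on gene length is argued against as the whole of it, since 2085 genes lay apart after its removal (599 to 977 in the other pairs), as is a joint trend on length and GC content, with 1889 genes apart after its removal (511 to 810) where 2796 of the genes with a GC value were apart before. Whether the 2 cultures responded unequally to 2-DG cannot be told apart from a general difference: stress genes differed by a median of 0.245 (at most 0.079 in the other pairs), but 18.5% of 1000 random lists of like expression differed as much. The first form of that test used the other pairs alone and would have favoured the unequal response; it was replaced because lists of many kinds differ in this pair, ribosomal protein genes by 0.961 and nuclear oxidative phosphorylation genes by 0.897. A test on depth was run and set aside for the joint trend. The 2 libraries held close totals, 17693102 and 17854701 counts. No biological explanation other than the response to 2-DG was tested.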

How the results depend on the processing

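Among the alternatives, DESeq2, its size factors and leaving out mitochondrial genes were chosen only after the results were seen. So was leaving out the first 2-DG library of day 3. Limma on log2(FPKM + 1) was the test first written, replaced by edgeR because counts were found. The others were planned. Of 665 alternative counts for 46 counts of genes, 603 stayed within 1.5 times, and of 44 for the 4 correlations, 30 stayed within their spread. Of 1886 alternatives for the 128 list results given, 1840 kept direction and call. Among those kept were all 128 with fry, which does not test a list against other genes. With an estimated correlation 45 lost the call, and 1 did without replicate 2 of the 2-DG group of day 3. Of 13780 alternatives for 1009 results on named genes, 13283 kept direction and call, 491 lost the call and 6 turned. Of the lost calls, 235 came with 1 library left out and 128 with limma on log2(FPKM + 1). The cause was not tested for any single call among these. On simulated data for HCl against control on day 3, where no low-count gene was changed, edgeR called 36% of 2-fold and 94% of 3-fold changes. Limma on log2(FPKM + 1) called 12% and 86% of the same changes. A call needs a log2 fold change of 1. The median estimate of the 2-fold changes was 0.974 with edgeR and 0.801 with limma, so limma called fewer of the known changes there.

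The replicate number as a block moved no count by over 1.5 times and ended 5 calls of named genes. It gave 111 for 106 genes for IWP2 against control on day 3, and same-numbered libraries were not taken as pairs: their deviations correlated with a median of 0.006 on days 3 and 5 (-0.11 to 0.293, over 0.1 in 2 of 66 pairs of groups) and of -0.005 on the other days (-0.06 to 0.065).

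With limma on log2(FPKM + 1), 39 of the 46 counts were lower by over 1.5 times, given here with the edgeR count in parentheses. In the order HCl, NaHCO3 and IWP2 against control, IWP2 with NaHCO3 against IWP2, 2-DG added against IWP2 with NaHCO3 and against IWP2, and HCl against IWP2, day 3 gave 863 (1833), 282 (706), 43 (106), 244 (552), 254 (620), 557 (1306) and 858 (1871) and day 5 gave 2121 (3456), 553 (1105), 571 (1171), 476 (1005), 1599 (2845), 1458 (2790) and 2228 (3676). In that order day 7 gave 1322 (2641), 863 (1888), 1692 (3034), 1611 (3079), 1562 (3013), 410 (1267) and 1084 (2423), and day 11 gave 2251 (3894), 1608 (3112), 1481 (2753), 1955 (3415), 2315 (3891), 417 (1069) and 461 (1211). The interaction gave 425 (681) on day 5, 1741 (2700) on day 7 and 2102 (3338) on day 11. The control gave 1803 (3131) for day 5 against 3, 4034 (6432) for day 7 against 0 and 836 (1919) for day 11 against 7. Effects that differed between days 11 and 7 numbered 1986 (3151) for HCl, 1167 (2105) for NaHCO3, 612 (1068) for IWP2, 832 (1398) for NaHCO3 beside IWP2 and 1095 (1778) for 2-DG.

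For IWP2 against control on day 3 (106), the count was 184 with no filter, 57 with a pseudocount of 0.1, 49 with day 3 alone and 163 without the first 2-DG library. For the interaction on day 3 (69), it was 175 with no filter, 111 with DESeq2, 14 with day 3 alone and 191 without that library. For 2-DG on day 3 (620), day 3 alone gave 368. The correlation of HCl and IWP2 changes was 0.289, 0.235 and 0.788 with no filter on days 3, 5 and 11, and 0.304, 0.226 and 0.786 with a pseudocount of 0.1.

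With 1 library left out, counts ranged on day 3 from 52 to 77 for IWP2 against control, 24 to 49 for the interaction, 339 to 503 for IWP2 with NaHCO3 against IWP2 (552 with all libraries), 418 to 2427 for 2-DG added to it (620), and 1087 to 2537 for 2-DG, NaHCO3 and IWP2 against IWP2 (1306). The number of genes whose 2-DG effect differed between days 3 and 5 ranged from 1765 to 3147 (1980 with all libraries). The correlations ranged from 0.179 to 0.335, 0.148 to 0.221, 0.568 to 0.648 and 0.793 to 0.841 on days 3, 5, 7 and 11.

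The direction turned for AFP with IWP2, NaHCO3 and 2-DG against IWP2 on day 7 (-2.661 to 0.196 with 1 library left out, the latter without IWP2 replicate 2), MYH6 in the interaction on day 7 (-3.478 to 0.612, the latter without NaHCO3 replicate 1), and NKX2-5 in the interaction on day 11 (-0.565 with limma on log2(FPKM + 1)). POU5F1 turned on day 11 without IWP2 replicate 1, to -1.364 for IWP2 against control (up to 6.082 with another library left out), 0.206 for IWP2, NaHCO3 and 2-DG against IWP2 (down to -9.604) and 0.59 for HCl against IWP2 (down to -6.856). A fold of exactly 0 was counted as a lost call, a choice made after 4 such values were seen.

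Scaling by deposited FPKM in place of TMM shifted the median of all genes by over 0.1 on the log2 scale for 2-DG on days 3 and 5 (-0.143 and -0.174), for 2-DG, NaHCO3 and IWP2 against IWP2 on these days (-0.147 and -0.14), for NaHCO3 on days 7 and 11 (-0.124 and -0.2), for the interaction on days 7 and 11 (0.179 and 0.134), for the control of days 7 and 11 against day 0 (0.169 and 0.102), and for NaHCO3 beside IWP2 between days 7 and 11 (-0.122). Upper-quartile scaling shifted it by -0.106 for 2-DG, NaHCO3 and IWP2 against IWP2 on day 5 and by 0.101 for the control of day 7 against day 0.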

Other observations

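No list in this part was chosen before its result was seen, though the lists themselves were fixed before the data were examined. Other gene groups also moved with time and treatment. In the control, WNT ligand genes rose in all 8 cases tested from day 0 to day 11 (adjusted p = 0.0011), with WNT2 at 4.32 ± 0.0707 FPKM from 0.02 ± 0. The list holds 19 such genes, and those silent on day 0 pass the filter only where a later group expresses them, which favours rises. BMP target genes rose in 8 of 12 cases (adjusted p = 2.68e-07), with MSX1, a homeobox factor, at 29.7 ± 0.658 from 0.065 ± 0.0212. Epicardial markers rose in 6 of 7 cases between days 3 and 5 of the control (adjusted p = 1.16e-04), with BNC1, a zinc finger factor, going from 0.045 ± 0.0212 to 9.66 ± 0.099 FPKM. On day 3 they rose in 4 of 7 cases with NaHCO3 against control (adjusted p = 4.82e-04) and in 4 of 7 with NaHCO3 beside IWP2 (adjusted p = 7.15e-04), with ALDH1A2, a retinoic acid enzyme, at 1.18 ± 0.099 and 0.185 ± 0.0778 FPKM in the first. Against control, the calls of BNC1, ALDH1A2, SEMA3D and BNC2 each ended in 1 alternative. Beside IWP2, the calls of BNC2, ALDH1A2 and BNC1 ended in 6, 5 and 2 of 14 alternatives and that of TCF21 in 0. BNC2 and ALDH1A2 lost theirs without IWP2 replicate 1 (edgeR adjusted p of 0.116 and 0.0979), IWP2 replicate 2 (0.116 and 0.188) or replicate 1 of IWP2 with NaHCO3 (0.325 and 0.289), where their alternatives ranged from 4.3e-07 to 0.325 and from 7.95e-05 to 0.289. Cholesterol synthesis genes rose on day 5 in 9 of 24 cases with HCl against control (adjusted p = 6.41e-06), and in 7 with 2-DG, with 1 lower (adjusted p = 7.39e-07). Definitive endoderm markers were higher in 5 of 8 cases in the interaction of NaHCO3 with IWP2 on day 5 (adjusted p = 2.05e-10), with HHEX, a homeobox factor of foregut endoderm, at 2.48 on the log2 scale. These counts were the same adjusted over the list alone.

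Genes of proton, bicarbonate and lactate transport, a list of direct interest for a change of pH, were called by camera in 0 of 36 comparisons, with an unadjusted p under 0.05 in 2 and a call by fry in 24. Blood cell markers were called by camera in 0 of 36, with an unadjusted p under 0.05 in 1 and a call by fry in 11.

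The structural RNAs RNA28S5 and RN7SK differed over 10-fold between the 2 libraries of 2 groups on day 3. In HCl replicates 1 and 2, RNA28S5 stood at 13300 and 662 CPM, RMRP at 69.3 and 0.484, and RN7SK at 220 and 10.9. In replicates 1 and 2 of IWP2 with NaHCO3, RNA28S5 stood at 281 and 2870, RMRP at 0.46 and 29.9, and RN7SK at 2.76 and 83.8. Smaller gaps were found in other groups, among them RNA28S5 at 385 and 1200 in replicates 1 and 2 of NaHCO3 on day 7, and RN7SK at 7.74 and 2.35 in those of IWP2 with NaHCO3 and 2-DG on day 3. POU5F1 stood at 1.95 ± 2.73 FPKM in the 2 IWP2 libraries of day 11, and AHSG at 13.2 ± 16.9 in those of day 7.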
